A study of Mus musculus with 2 samples.

How the data were processed

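Single-cell RNA was measured in live CD45+ cells sorted from subcutaneous B16.SIY melanomas of B6 mice at day 14 after injection. B16.SIY is a mouse melanoma line that carries a model antigen. Before injection the tumour cells were transduced with a lentivirus coding for a control shRNA or for an shRNA against Decr2, and cultured with puromycin at 1.5 µg/mL for 3 days, per the labels. The tumours were digested with enzymes and enriched on a density gradient before the sort, per the labels' protocols. There were 2 libraries, 1 per group. The number of mice behind each library was not given in the sources used here.

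The deposited counts were unique molecular identifiers (UMIs) per gene and cell barcode, made by the authors with Cell Ranger 6.1.2 on the mm10 mouse genome, per the submitters' processing notes and the file headers. Seurat 4.3 is named in the same notes, and the deposited values were whole counts with no normalisation. Each barcode held at least 500 UMIs, so barcodes had been called as cells before deposit. The aligner settings and the annotation release were not given in the sources used here. The files listed 32285 genes, of which 32158 (99.6%) were located through their Ensembl gene ID in GENCODE M21 on GRCm38, the same assembly as mm10.

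Cells were kept with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs. Doublets were scored per library with Scrublet in scanpy 1.11.5, and the highest scores were removed at 0.8% of barcodes per 1000 barcodes. The control library kept 8947 of 11335 barcodes and the knockdown library 6886 of 9542. Counts were scaled to 10000 per cell and log-transformed, and both libraries were clustered together with 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1, with no batch integration. T-like cells were clustered again by themselves. Clusters were named from 25 cell type lists fixed before the data were examined. The exact naming rule was set afterwards: at least 3 list genes at a log2 level 1 or more above the median cluster and in at least 10% of cells. T subclusters were split on Cd8a or Cd8b1 in 50% of cells, Cd4 in 30% and Foxp3 in 30%, and those that met none of these were kept together as other T-like cells. A CD8-detected subcluster whose 10 leading genes held more markers of another list than of its own was set aside, and its share is given by itself.

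Shares of cells carry exact Clopper-Pearson 95% intervals. UMIs were summed per library and class and expressed as CPM, scaled by the total of that class, with exact Poisson intervals, and ratios of knockdown to control carry exact conditional binomial intervals. All of these cover counting error only. With 1 library per group no p-value was computed and no genes were counted as different. A class was compared with at least 100 cells in each library, which left 10 classes. That melanoma-like cells met this rule, and the setting aside of the CD8-detected subcluster, were settled after the data had been seen. Log2 ratios in lists used a pseudocount of 10 CPM, and log2 ratios of single genes under alternatives a pseudocount of 1 CPM. The median log2 ratio of a gene list was placed as a percentile among 10000 random lists of the same size, drawn from 20 bins of mean expression. This describes these 2 libraries, not the conditions. The median log2 ratio of genes at 50 CPM or more lay between -0.02 and 0.01 in every class. Cycling shares counted cells with a UMI of at least 2 proliferation genes after each cell was thinned to 1000 UMIs.

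The 22 programme lists, fixed before the data were examined, covered cytotoxic effectors, exhaustion, naive and memory genes, T cell activation, tissue residency, proliferation, type I interferon, interferon gamma, MHC class I and class II, alternative and inflammatory macrophage activation, myeloid chemokines, hypoxia, glycolysis, ferroptosis, NRF2, fatty acid oxidation, lipid uptake, cholesterol synthesis, dissociation stress and checkpoint ligands. Named genes followed a rule fixed at the same time. It took genes with at least 30 UMIs over both libraries and at least 50 CPM in 1 library, ranked by the interval bound nearest to a ratio of 1. The 10 highest and 10 lowest were named in CD8 T-like cells and macrophage-like cells, and the 5 highest and 5 lowest elsewhere. Mitochondrial, ribosomal, haemoglobin, Gm, Rik, immune receptor segment and melanoma marker genes were left out of this ranking. Up to 4 members of a discussed list on the side of its median were also named, with up to 2 on the other side. Which lists are discussed in which class was chosen after their values were seen. Some genes that this rule took are not reported here, and none was put in their place.

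The scripts were tested on counts simulated with Poisson error alone from the summed UMIs of the CD8 T-like cells. Of the ratio intervals, 95.5% held the true ratio. Genes whose UMIs gather in few cells were not simulated. This therefore checks the computation, not how often the intervals hold in these data. Intervals lay on the right side of 1 for 100% of genes simulated at a fold of 2, 100% at 0.5, 100% at 1.5 and 88% at the inverse of 1.5. Of the unchanged simulated lists, whose genes were drawn independently of each other, 4% fell outside the central 95% of random lists. Alternatives covered doublet removal, the cell filter, clustering resolution, separate clustering, thinning, a per-cell CD8 gate, pseudocounts, UMI minimums, scaling, equal weight per cell, and cells left out. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, anndata 0.12.19 and matplotlib 3.10.9 were used.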

Results

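The data describe immune cells sorted from mouse melanomas grown from control cells or from cells with an shRNA against Decr2, the peroxisomal 2,4-dienoyl-CoA reductase that acts on polyunsaturated fatty acids. There was 1 control shRNA library and 1 Decr2 knockdown library, so no difference below has a replicate check. The control library held 47538493 UMIs in 11335 barcodes and the knockdown library 55417986 UMIs in 9542 barcodes. Kept cells had a median of 2877 UMIs in the control library and 4442 in the knockdown library, so cells of the knockdown library were deeper. Intervals in brackets are exact 95% intervals for counting error alone. Xist was detected at 579 and 668 CPM in the control and knockdown libraries and Ddx3y had 0 UMIs in both, with upper limits of 0.0941 and 0.0799 CPM.

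Decr2, the targeted gene (ENSMUSG00000036775, chromosome 17, 26081208 to 26090337, GRCm38), was at 5.25 CPM in all kept control cells and 4.42 CPM in all kept knockdown cells, a ratio of 0.841 (0.690 to 1.03). In melanoma-like cells, the cell type that received the shRNA, Decr2 had 19 UMIs in the control library and 10 in the knockdown library. These counts gave 6.42 (3.87 to 10.0) and 3.62 (1.73 to 6.65) CPM and a ratio of 0.563 (0.234 to 1.27). Decr2 in immune cells was at 5.16 and 4.49 CPM, a ratio of 0.870 (0.707 to 1.07). The mitochondrial relative Decr1 was at 68.3 and 64.7 CPM in melanoma-like cells, a ratio of 0.948 (0.771 to 1.17). A lower Decr2 level in the knockdown library was not detectable at this depth, and the CD45 sort removed most cells in which the label could be checked.

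The first comparison asked how the immune infiltrate differed in composition. NK-like cells were the largest class, at 37.5% (36.5 to 38.5) of control cells and 35.0% (33.9 to 36.2) of knockdown cells. Regulatory T-like cells, which carry Foxp3, took 2.47% (2.16 to 2.81) of control cells and 3.53% (3.11 to 3.99) of knockdown cells. CD8 T-like cells took 18.2% (17.4 to 19.0) and 16.96% (16.1 to 17.9). A CD8-detected subcluster with high Ccr7, Lef1 and Tcf7, set aside from this class, took 1.78% (1.51 to 2.07) and 2.93% (2.55 to 3.36), but 4.12% and 4.31% under the looser cell filter. The subcluster was set aside on 1 leading gene, Ccr7 of the mature dendritic list, against 0 of its own list. A UMI of Cd8a or Cd8b1 was found in 75.6% of the cells of the subcluster. With it included, CD8 T-like cells were 19.98% (19.2 to 20.8) and 19.9% (19.0 to 20.9), a difference of -0.0889 points (-1.35 to 1.18). There were then 8.09 CD8 T-like cells per regulatory T-like cell in the control library and 5.64 in the knockdown library, and 7.37 and 4.81 without the set-aside subcluster. Under the stricter cell filter the NK-like difference shrank from -2.46 to -0.766 points (-2.42 to 0.896), and the CD8 T-like difference without the subcluster, -1.25 points, had an interval that included 0 under this filter and at resolution 2. With separate clustering the subcluster did not form, and the CD8 T-like difference was -0.402 points (-1.67 to 0.869). Among all T-like cells, regulatory T-like cells made up 7.29% (6.39 to 8.27) and 10.5% (9.26 to 11.8).

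Myeloid and B-like classes had similar shares in the 2 libraries. Monocyte-like cells took 8.82% and 8.29%, macrophage-like cells 4.19% and 4.56%, conventional dendritic-like cells 4.82% and 5.13%, plasmacytoid dendritic-like cells 1.31% and 1.60%, and B-like cells 3.45% and 3.25%. For each of these 5 classes the interval of the difference included 0, though it left out 0 for monocyte-like cells with separate clustering (-2.07 to -0.266 points) and for conventional dendritic-like cells under the stricter filter (0.0229 to 1.59). The border between monocyte-like and macrophage-like cells moved with resolution. Macrophage-like cells numbered 375 control and 314 knockdown in the main clustering, 127 and 93 at resolution 0.5, and 587 and 454 at resolution 2. Monocyte-like cells numbered 1021 and 789 at 0.5, and 545 and 419 at 2. CD4 T-like cells took 1.89% and 1.95%, and other T-like cells 9.55% and 8.31%. These 2 classes rest on the clustering, since with each library clustered on its own CD4 T-like cells took 0% and 3.95% and other T-like cells 10.9% and 7.14%. Mast cell- or basophil-like cells took 0.425% and 0.349%. Melanoma-like cells that passed the CD45 sort took 1.36% (1.13 to 1.63) and 2.57% (2.21 to 2.97), and unnamed clusters 4.26% and 5.56%. The melanoma-like difference of 1.21 points (0.761 to 1.67) depends on the cell filter, with 1.08% and 1.34% under the stricter filter, a difference of 0.264 (-0.110 to 0.655), and 2.59% and 3.02% under the looser one, a difference of 0.436 (-0.0582 to 0.940). A CD8 gate applied per cell at equal depth gave 15.1% (14.4 to 15.9) and 14.2% (13.3 to 15.1) of the 8505 control and 6486 knockdown cells deep enough to thin, and of B-like cells 0% and 0.463% passed it.

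**Figure D1:**
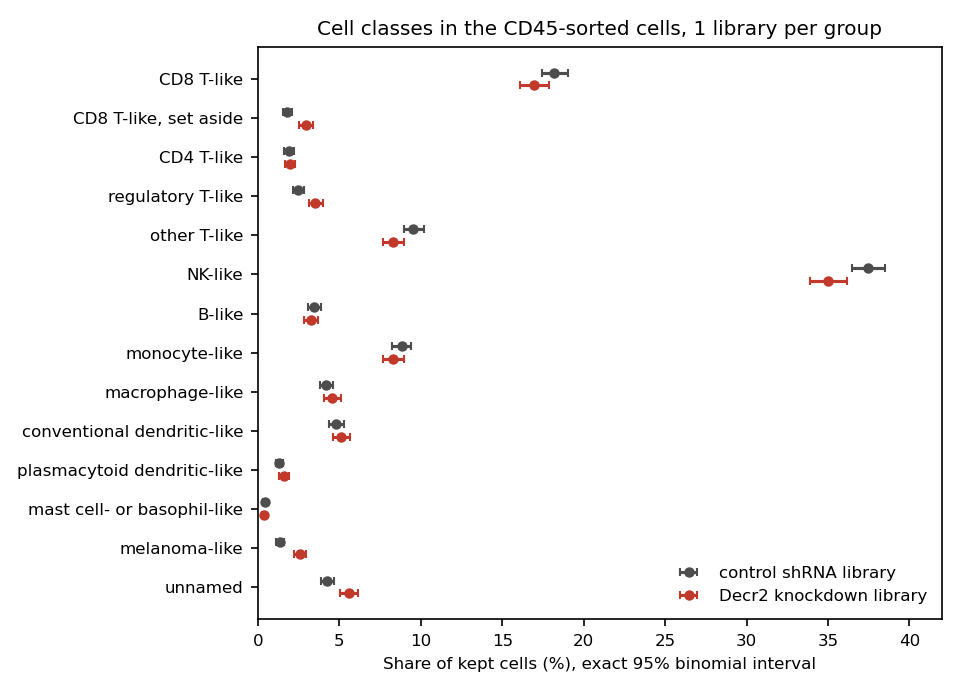
Share of kept cells (x axis, percent) in each cell class (y axis) for the control shRNA library (grey) and the Decr2 knockdown library (red), with exact 95% binomial intervals as bars. Regulatory T-like cells lie at 2.47% and 3.53%. Melanoma-like cells lie at 1.36% and 2.57%, a difference whose interval includes 0 under the stricter and looser cell filters.

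The next comparison asked how CD8 T-like cells differed in gene expression. Gzmc, a granzyme (ENSMUSG00000079186, chromosome 14, 56231441 to 56234656), was at 149 CPM in the control library and 362 CPM in the knockdown library, a ratio of 2.43 (2.31 to 2.55). Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156) and Hspa1b, inducible heat shock proteins, were at ratios of 0.395 (0.378 to 0.414) and 0.382 (0.357 to 0.409). The chemokines Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518) and Ccl4 were at 0.680 (0.671 to 0.689) and 0.643. Counts of near-identical copies such as Hspa1a and Hspa1b, and of the granzyme family, can be shared and are uncertain for single members.

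Other genes higher in CD8 T-like cells of the knockdown library were Neurl3 (1.74), Nr4a3 (1.61), Serpinb6b (1.55), Gzmf (1.50), Kdm2b (1.45), Gramd3 (1.44), Mt1 (1.43), Lgals3 (1.42) and Zfp36l2 (1.41). Genes lower were Cd7 (0.514), Hist1h2ap (0.595), Cd226 (0.631), Jun (0.662) and Cd160 (0.670). Without cells that had UMIs of 2 proliferation genes, Gzmf and Mt1 turned lower, at log2 ratios of -0.16 and -0.48. This setting used counts without thinning, so it removed deep cells more easily and was not a test of proliferation alone. It left out 76.9% of control and 90.0% of knockdown CD8 T-like cells. The subclusters of the class differed in share. A subcluster led by Gzmk, Cxcr6 and Lag3 made up 12.95% (11.4 to 14.7) of control and 3.51% (2.53 to 4.73) of knockdown CD8 T-like cells, and one led by Pdcd1 and Havcr2 made up 20.4% (18.5 to 22.5) and 30.4% (27.8 to 33.1). Cxcr6 and Lag3 were among the leading genes of both, and their median depths were 4159 and 8342 UMIs. CD8 T-like cells had medians of 6481 UMIs in the control and 11833 in the knockdown library. Whether depth alone moved cells between these subclusters was not tested. The subcluster led by Gzmf, Gzmc and Mt1 made up 7.98% and 10.4%.

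Of the 14 cytotoxic effector genes, 9 were lower in CD8 T-like cells of the knockdown library and 5 were higher, with a median log2 ratio of -0.11 (percentile 0.02 among random lists). Ccl3 and Xcl1 were at ratios of 0.729 and 0.736 beside Ccl4 and Ccl5, and Gzmc and Gzmf went the other way. Of 12 exhaustion genes, 9 were lower, with a median of -0.13 (percentile 0.02). Lag3 was at 0.778 (0.730 to 0.830), Tox at 0.818 (0.775 to 0.864) and Rgs16 at 0.906 (0.874 to 0.940). Pdcd1, which codes for PD-1, was at 1.01 (0.968 to 1.05) and Havcr2, which codes for TIM-3, at 1.12 (1.04 to 1.21). The same list had medians of 0.95 (percentile 100, 4 of 5 genes higher) in CD4 T-like and 0.20 (percentile 98.97, 6 of 9 higher) in conventional dendritic-like cells. The former was 0.36 with no UMI minimum, and the latter 0.034 (percentile 63.9, inside the central 95%) with equal weight per cell. Of 10 naive and memory genes, 9 were higher, with a median of 0.27 (percentile 100), and Klf2 was at 0.820. None of the 9 reached 50 CPM, and the median was 0.10 with a pseudocount of 50 CPM and 0.53 with 1 CPM. The same list had medians of 0.48 in regulatory T-like and 0.50 in macrophage-like cells. The set-aside subcluster, with high Ccr7, Lef1 and Tcf7, was not part of the CD8 T-like class compared here. Of 10 cholesterol synthesis genes, 9 were lower, with a median of -0.27 (percentile 0), among them Idi1 (0.771), Hmgcs1 (0.775) and Fdps (0.798), while Srebf2 was at 1.01. With equal weight per cell the cholesterol median was -0.13 and the cytotoxic median -0.17. Tissue residency genes had a median of -0.05 (percentile 15.9) and T cell activation genes 0.06 (percentile 97.3).

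In regulatory T-like cells of the knockdown library, activation genes were higher. Of 8 measured, 7 were higher, with a median log2 ratio of 0.22 (percentile 100). Il2ra was at a ratio of 1.65 (1.36 to 2.02), Cd69 at 1.41 (1.12 to 1.79), Icos at 1.29 (1.15 to 1.45) and Tnfrsf18 at 1.17 (1.07 to 1.28), while Tnfrsf9 was at 0.920. Other lists, some of them typical of CD8 T or myeloid cells, moved with them. Of 9 cytotoxic effector genes, 8 were lower, with a median of -0.64 (percentile 0), all 5 measured myeloid chemokines were lower, with a median of -0.94 (percentile 0), and 9 of 10 exhaustion genes, with a median of -0.25 (percentile 0.13). Naive and memory genes had a median of 0.48 (percentile 100), with 6 of 7 higher. The chemokine median was -0.085 (percentile 13.4) with no UMI minimum, and the exhaustion median -0.17 (percentile 3.84) with equal weight per cell, both inside the central 95%. All 9 measured cholesterol synthesis genes were lower, with a median of -0.53 (percentile 0), among them Hmgcs1 (0.583), Insig1 (0.637), Fdps (0.647) and Idi1 (0.676), a median that was -0.31 with a pseudocount of 50 CPM. Il7r (2.49), Carhsp1 (2.49), Rab43 (2.22) and Areg (1.68), which codes for amphiregulin, were among the highest genes by rank. Gzma was at 1.93 but at 1.00% of its level in NK-like cells. Among the lowest were Hspa1a (0.261), Serpinb9 (0.283), Hspa1b (0.323), Cd8b1 (0.343) and Plac8 (0.393), the last at 2.78% of its level in monocyte-like cells. Serpinb9 was at 10.7% of its level in NK-like cells and Cd8b1 at 9.75% of its level in CD8 T-like cells. A UMI of Cd8a or Cd8b1 was found in 15.5% of regulatory T-like cells. Whether a different admixture of other cells moved the lists of this class, activation genes included, was not tested. Areg and Cd8b1 changed side without cells with 2 proliferation genes, and Gzma with doublets kept, at log2 ratios of -0.16, 0.68 and -0.69.

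In NK-like cells of the knockdown library Tsc22d3, a glucocorticoid-induced gene, was at a ratio of 1.66 (1.54 to 1.78), Nrarp at 1.40 (1.27 to 1.54) and Dusp2 at 1.31 (1.28 to 1.34). H2-Eb1 (1.59) and H2-Aa (1.47) were at 1.02% and 0.899% of their level in conventional dendritic-like cells. Hspa1b (0.657), Hist1h1b (0.6668), Rsrp1 (0.708) and Hspa1a (0.711) were lower. Hist1h1b turned higher without cells with UMIs of 2 proliferation genes, at a log2 ratio of 0.13. Of 10 naive and memory genes, 8 were higher, with a median log2 ratio of 0.22 (percentile 100), among them Tcf7 (1.28) and Lef1 (1.12), and Klf2 was at 0.971. The median was 0.11 with a pseudocount of 50 CPM, and the same list had its highest median, 0.50, in macrophage-like cells. In CD4 T-like cells Il17a had 86 UMIs in the control library and 1 in the knockdown library, with 40.7% of the control UMIs in 1 cell. Hspa1a (0.406), Egr1 (0.499) and Hspa1b (0.505) were lower. Spp1 (0.234) had 81.5% of its control UMIs in 1 cell, and Ccl4, Ccl3, Il1b, Acod1 and Ccl6 were higher with 93.4%, 93.6%, 98.2%, 87.7% and 75.7% of the knockdown UMIs in 1 cell. Spp1 and Ccl6 were at 2.53% and 4.78% of their level in macrophage-like and monocyte-like cells. Without the cell with most of their UMIs, Il1b and Spp1 changed side, at log2 ratios of -1.20 and 0.14. Without cells with UMIs of 2 proliferation genes, Ccl4 and Acod1 changed side, at -0.36 and -2.14.

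In macrophage-like cells of the main clustering the inflammatory genes were higher in the knockdown library. Gene levels in macrophage-like and monocyte-like cells were not compared at other resolutions, where the border between these classes moved. All 9 measured members of the inflammatory list were higher, with a median log2 ratio of 0.37 (percentile 99.94). Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007) was at 248 and 476 CPM, a ratio of 1.92 (1.67 to 2.21), Cd86 at 1.40 (1.17 to 1.68), Nos2 at 1.32 (1.07 to 1.62) and Il1b at 1.21 (1.14 to 1.28). Inhba, a subunit of activin A (ENSMUSG00000041324, chromosome 13, 16011851 to 16031621), was at 507 and 1269 CPM, a ratio of 2.503 (2.28 to 2.75). Arg1, arginase 1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), was at 298 and 166 CPM, a ratio of 0.556 (0.470 to 0.658).

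Other genes higher in macrophage-like cells were Rrad (2.89), Flrt3 (2.27), Slamf7 (2.05), Il7r (1.96) and Acod1 (1.89), the enzyme that makes itaconate. Pgf was at a ratio of 10.7 (5.96 to 21.2) with 42.1% of its knockdown UMIs in 1 cell, and Retnla and Lyz1 had 99.88% and 97.2% of theirs in 1 cell. T cell genes moved in this class as well, with 9 of 10 naive and memory genes higher at a median log2 ratio of 0.50 (percentile 100), and 0.25 (percentile 97.03, inside the central 95%) with equal weight per cell. Of 13 cytotoxic effector genes, 10 were lower, with a median of -0.31 (percentile 0). Genes lower were Cxcr6 (0.328), Rnaset2b (0.352), Atr (0.363), Cx3cr1 (0.397), Serpinb2 (0.409), Ifng (0.484), Ssrp1 (0.519), Pf4 (0.531) and Ccl5 (0.611). Cx3cr1 had 53.5% of its control UMIs in 1 cell, and Ccl5 and Ifng were at 16.4% and 17.3% of their level in NK-like cells. Serpinb2 turned higher without cells with UMIs of 2 proliferation genes and Pf4 with doublets kept, at log2 ratios of 0.80 and 0.13.

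Of 10 NRF2 response genes, 9 were higher in macrophage-like cells, with a median of 0.36 (percentile 99.99), among them Sqstm1 (1.44), Nfe2l2 (1.32), Slc7a11 (1.28) and Txnrd1 (1.26), with Prdx1 at 0.960. With equal weight per cell the NRF2 median was 0.24 and Nfe2l2 turned lower, at -0.12. All 11 glycolysis genes were lower, with a median of -0.27 (percentile 0.01), among them Hk2 (0.718), Pfkl (0.787), Gpi1 (0.794) and Eno1 (0.811). Type I interferon genes had a median of 0.26 (percentile 99.92) with Ifit2 (1.48), Isg15 (1.38), Ifit1 (1.36) and Irf7 (1.35) higher and Ifit3 at 0.872. This median was 0.045 without the most abundant cluster and 0.14 (percentile 95.6) with equal weight per cell, both inside the central 95%. Interferon gamma genes had a median of 0.18 (percentile 99.4) with Gbp5 (1.89), Igtp (1.55), Socs1 (1.44) and Iigp1 (1.40) higher and Cxcl9 and Cxcl10 at 0.882 and 0.832. Cxcl10 turned higher with doublets kept and without cells with UMIs of 2 proliferation genes, at 0.20 and 0.13. The alternative activation list had a median of 0.32 (percentile 99.8) with Mrc1 at 1.59 and Chil3 at 0.721. The cholesterol list had a median of -0.40 (percentile 0.03), with 7 members lower and 2 higher, Fdps at 0.567 and Srebf2 at 0.876. With members of at least 100 UMIs these medians became -0.0039 and 0.078, and with equal weight per cell 0.24 (percentile 95.5) and -0.022 (percentile 38.2), all inside the central 95%. Chil3 turned higher without cells with UMIs of 2 proliferation genes, at 0.10.

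In monocyte-like cells the interferon gamma genes were higher and the hypoxia genes lower in the knockdown library. Of 14 interferon gamma genes, 13 were higher, with a median log2 ratio of 0.31 (percentile 100). Cxcl9, a ligand of CXCR3 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), was at 342 and 697 CPM, a ratio of 2.04 (1.91 to 2.18). Iigp1 (1.54), Gbp2 (1.42) and Irf1 (1.32) were also higher, and Cxcl10 was at 0.988. Type I interferon genes had a median of 0.22 (percentile 99.99), with Irf7 (1.36), Bst2 (1.35), Oasl2 (1.31) and Usp18 (1.23) higher, Ifi27l2a at 0.997 and Rsad2 at 0.916. Of 10 hypoxia genes, 9 were lower, with a median of -0.36 (percentile 0), among them Hilpda (0.551), Hk2 (0.653), Slc2a1 (0.687) and Ldha (0.791), and P4ha1 was at 1.01. All 11 glycolysis genes were lower, with a median of -0.29 (percentile 0.01), with Tpi1 at 0.718 and Eno1 at 0.782. All 11 MHC class I genes were higher, with a median of 0.17 (percentile 99.8). Of 10 MHC class II genes, 6 were lower, with a median of -0.16 (percentile 0.17), which was -0.30 with members of at least 100 UMIs and -0.11 (percentile 3.31, inside the central 95%) with equal weight per cell. The cytotoxic effector list had a median of 0.17 (percentile 99.84), with 9 of 12 higher. Apoe (2.21), Klf9 (2.31), Cxcl1 (1.76) and Chil3 (1.68) were higher by rank, and Arg1 (0.225), Spp1 (0.261), Ccl8 (0.339), Hspa1b (0.486) and Basp1 (0.492) lower. Ccl8 had 82.6% of its control UMIs in 1 cell, and Arg1 47.3% of its knockdown UMIs in 1 cell. Arg1, Basp1, Ccl8 and Spp1 were at 16.6%, 15.8%, 9.82% and 9.02% of their level in macrophage-like cells. Of 8 alternative activation genes, 7 were lower, with a median of -0.38 (percentile 0), Ccl24 at 0.718 and Msr1 at 0.915. This median was -0.58 with a pseudocount of 1 CPM, -0.18 with 50 CPM and -0.20 with equal weight per cell. Cxcl1 turned lower without cells with UMIs of 2 proliferation genes, at -0.37, and Ccl8 higher, at 1.78.

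**Figure D2:**
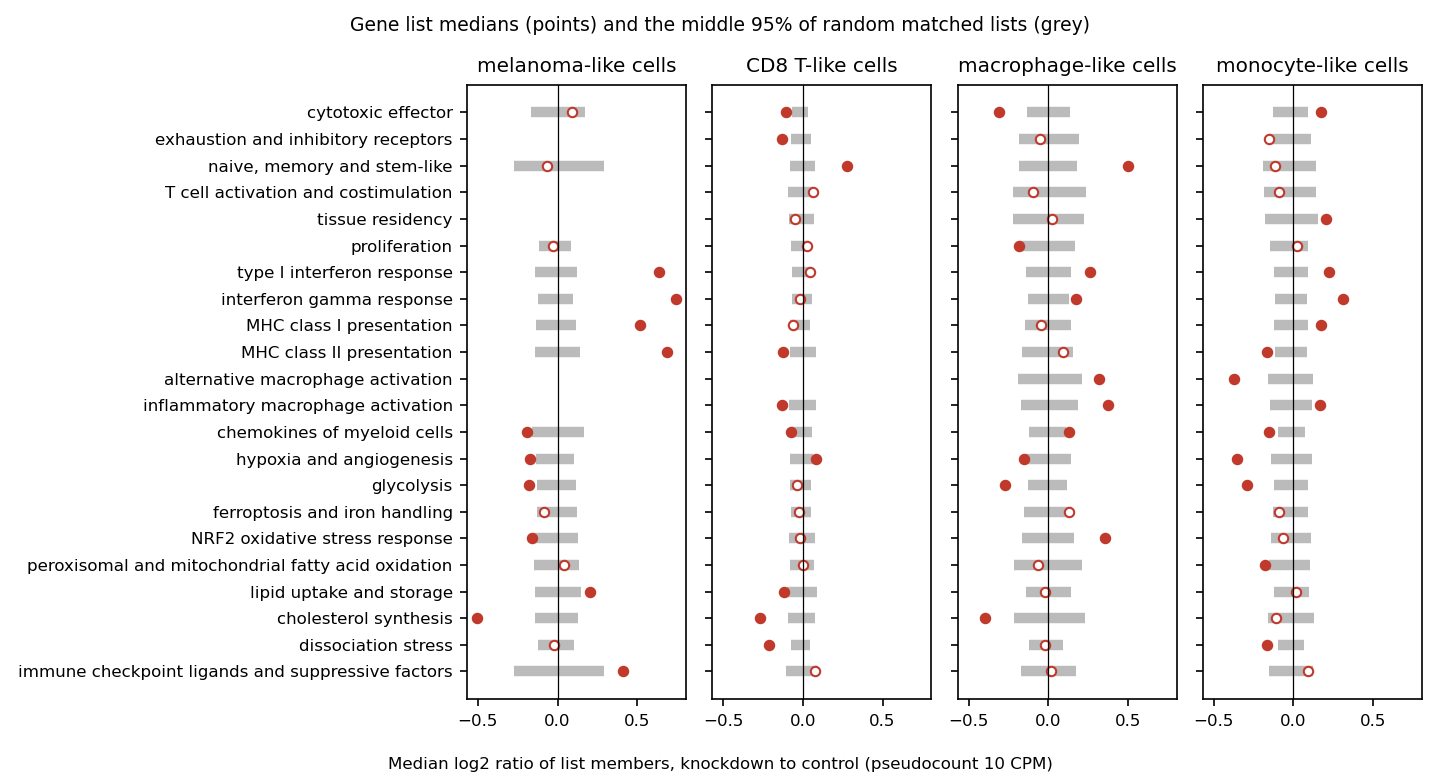
Median log2 ratio of knockdown to control (x axis, pseudocount 10 CPM) of each gene list (y axis) in 4 cell classes. Points are list medians, filled where they lie outside the central 95% of random matched lists, which the grey bars show. The interferon gamma median lies at 0.74 in melanoma-like and 0.31 in monocyte-like cells.

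**Figure D3:**
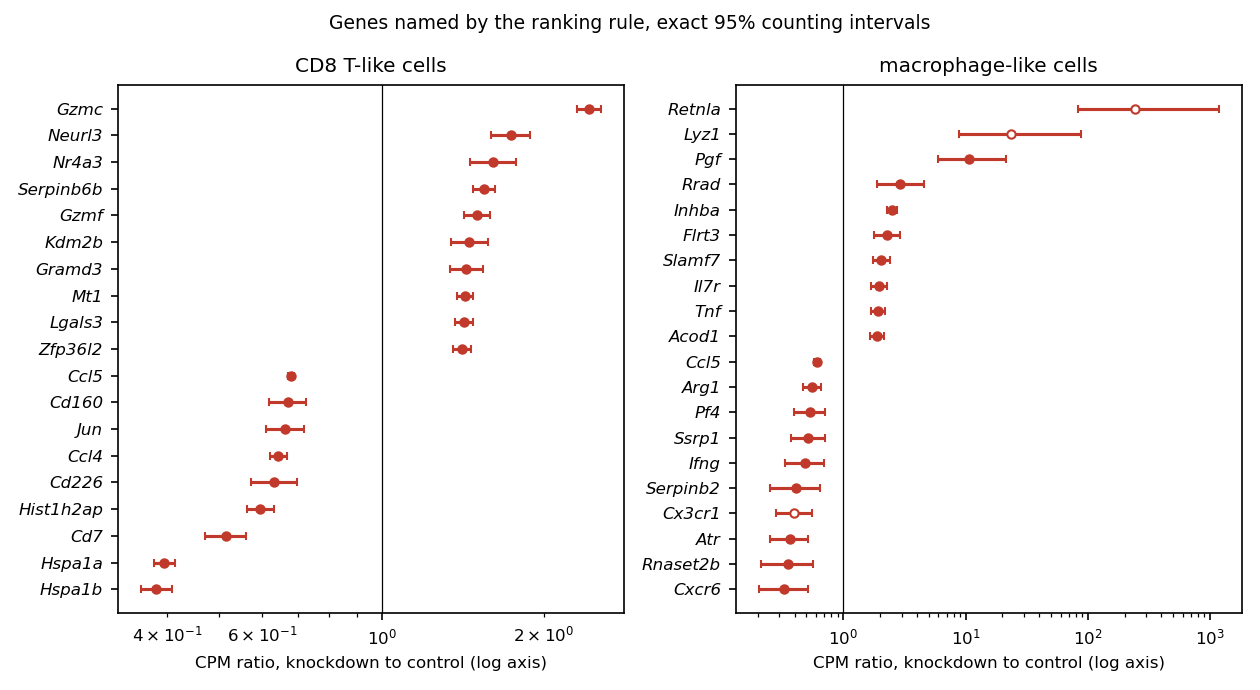
Ratio of CPM, knockdown to control (x axis, log scale), of the reported genes named by rank (y axis) in CD8 T-like and macrophage-like cells, with exact 95% counting intervals as bars. Open points mark genes with over 50% of the UMIs of a library in 1 cell, such as Retnla and Cx3cr1.

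In conventional dendritic-like cells of the knockdown library Hspa1a was at 2271 and 871 CPM, a ratio of 0.384 (0.366 to 0.402), and Hspa1b (0.386), Lrrc25 (0.517) and Jun (0.654) were also lower. Gzma (0.578) was at 1.29% of its level in NK-like cells. Ccl22 (2.76), Ccr7 (2.75), Cacnb3 (2.71), Fscn1 (2.41) and Tbc1d4 (2.41) were higher, beside the cluster they define, which made up 15.1% (11.8 to 18.8) and 21.8% (17.6 to 26.5) of the class. Of 14 interferon gamma genes, 12 were higher, with a median log2 ratio of 0.24 (percentile 100), among them Cd274 (1.68), which codes for PD-L1, Socs1 (1.59) and Gbp5 (1.30), with Ciita at 0.966 and Cxcl10 at 0.952. Type I interferon genes had a median of 0.19 (percentile 99.87), with Ifit2 (1.53), Rsad2 (1.44), Usp18 (1.39) and Ifit3 (1.34) higher, Ifi27l2a at 0.905 and Rtp4 at 0.7996. The type I median was 0.078 (percentile 93.7) with equal weight per cell and 0.13 (percentile 84.5) without the most abundant cluster, both inside the central 95%, and Ifit3 turned lower with doublets kept, at -0.17. MHC class I genes had a median of 0.14 (percentile 99.7), with H2-Q7 (1.35), Tap1 (1.12), Tapbp (1.10) and Psmb9 (1.10) higher, Tap2 at 0.999 and H2-D1 at 0.984.

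In B-like cells the interferon gamma genes had a median log2 ratio of 0.58 (percentile 100), with 9 of 12 higher. With members of at least 100 UMIs it was 0.24 (percentile 96.3), inside the central 95%. Gbp4 (1.94), Cxcl10 (1.91) and Gbp2 (1.81) were higher, and Irf1 (0.872) and Cd274 (0.725) were lower. Cxcl10 turned lower with doublets kept and under the stricter cell filter, at -0.95 and -1.24. Gbp2 turned lower without cells with UMIs of 2 proliferation genes, at -0.14. MHC class I genes had a median of 0.31 (percentile 99.98), with Psmb9 (1.64), Tapbp (1.61), Tap1 (1.43) and Tap2 (1.36) higher, H2-Q7 at 0.897 and H2-D1 at 0.857. S100a6 (2.89), Ptpn22 (2.79), Creld2 (4.69), Hsp90b1 (2.35) and Mzb1 (2.27) were higher, with 66.7%, 47.5% and 49.0% of the knockdown UMIs of the last 3 in 1 cell. Hist1h3e (0.241), Wfdc17 (0.335), Snf8 (0.427), Vpreb3 (0.542) and Fcer2a (0.568) were lower. S100a6 and Wfdc17 were at 4.75% and 4.495% of their level in monocyte-like cells. Mzb1 turned lower without cells with UMIs of 2 proliferation genes, at -0.17. In plasmacytoid dendritic-like cells Cd8a (2.82), Ilf2 (2.71), Fcgrt (2.63), Nasp (2.32) and Lgals3 (1.85) were higher. Lyz2 (0.146), Vdac3 (0.399), Gzma (0.419), Fos (0.507) and Hspa1b (0.519) were lower, with 88.0% of the control UMIs of Lyz2 in 1 cell, without which it turned higher, at a log2 ratio of 0.16. Gzma was at 0.909% of its level in NK-like cells, Lgals3 at 3.14% of its level in macrophage-like cells and Lyz2 at 0.732% of its level in monocyte-like cells.

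In melanoma-like cells, the tumour cells that passed the sort, interferon and antigen presentation genes were higher in the knockdown library, beside the immune cell gene Ptprc. Of 14 interferon gamma genes, 13 were higher, with a median log2 ratio of 0.74 (percentile 100). Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889) was at 253 and 599 CPM, a ratio of 2.37 (2.17 to 2.58), Gbp4 at 2.26 (1.92 to 2.66), Iigp1 at 2.03 (1.82 to 2.27) and Igtp at 1.98 (1.78 to 2.20). Of 11 MHC class I genes, 10 were higher, with a median of 0.52 (percentile 100). Tap1, the peptide transporter (ENSMUSG00000037321, chromosome 17, 34187553 to 34197225), was at 1.87 (1.62 to 2.16), Tap2 at 1.57, Tapbp at 1.53 and Psmb8 at 1.51. All 9 measured MHC class II genes were higher, with a median of 0.69 (percentile 100), among them H2-Eb1 (1.92), H2-DMa (1.86), H2-Aa (1.83) and H2-Ab1 (1.74). Ptprc was at 22.0 and 32.9 CPM in these cells, a ratio of 1.50 (1.08 to 2.09). RNA of immune cells in these droplets was tested only for the interferon gamma list, and stays open for MHC class I and class II genes. With equal weight per cell the interferon gamma median was 0.24 (percentile 97.3, inside the central 95%), the class I median 0.22 and the class II median 0.41, and Iigp1, Tap1 and Tap2 turned lower, at log2 ratios of -0.23, -0.31 and -0.43.

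Type I interferon genes had a median of 0.63 (percentile 100) in melanoma-like cells, with Oasl2 (2.48), Ifit3 (2.21), Isg15 (2.09) and Rtp4 (1.87) higher and Rsad2 at 0.832. All 10 cholesterol synthesis genes were lower, with a median of -0.51 (percentile 0), among them Insig1 (0.493), Idi1 (0.549), Hmgcs1 (0.671) and Sqle (0.691). All 11 glycolysis genes were lower, with a median of -0.18 (percentile 0.1), among them Slc2a1 (0.714), Eno1 (0.799), Gapdh (0.822) and Pfkl (0.866). The ferroptosis list, with Gpx4 at 0.856, Ftl1 at 0.805, Hmox1 at 0.863, Sat1 at 0.865 and Tfrc at 1.01, had a median of -0.08 (percentile 10.4). The fatty acid oxidation list, with Eci2 at 0.921, had a median of 0.04 (percentile 74.5). That list had medians of -0.18 in monocyte-like (percentile 0.8, 9 of 11 lower) and in conventional dendritic-like cells (percentile 1.76, 7 of 10 lower), which were -0.074 and -0.087 with a pseudocount of 50 CPM. With members of at least 100 UMIs the monocyte-like median lay inside the central 95% (percentile 3.67). NRF2 genes had a median of -0.16 (percentile 1.66), with Txnrd1 (0.845), Nfe2l2 (0.886) and Sqstm1 (0.892). With equal weight per cell the medians were -0.37 (percentile 2.75) for cholesterol synthesis, -0.11 (percentile 18.3) for glycolysis and -0.30 (percentile 7.05) for NRF2 genes, all inside the central 95%, and Sqstm1 and Rsad2 turned higher, at log2 ratios of 0.24 and 0.63. Without the 3 deepest cells of each library the glycolysis median was -0.15 (percentile 3.31), also inside. Trim30a (2.70), Phf11d (2.55) and Nfkbia (2.48) were higher, Nfkbia at 2.90% of its level in monocyte-like cells. Cck (9.98) had 99.93% of its knockdown UMIs in 1 cell. Cxcl9 (0.0372), Ccl2 (0.242), Dcn (0.250), Timp1 (0.356) and Rarres2 (0.400) were lower, with 94.8%, 73.0%, 74.3%, 77.8% and 97.6% of the control UMIs in 1 cell. Melanoma-like cells had a median of 4932 UMIs in the control and 1199 in the knockdown library, and 50% of their UMIs came from 21 and 13 cells. Without the 92 control and 106 knockdown cells that had UMIs of 2 proliferation genes, Cxcl10, Phf11d, Iigp1, Tap1, Tap2 and Tapbp were lower, at -0.26, -0.32, -2.89, -0.72, -0.99 and -0.10. In the cells left, Hmgcs1, Idi1, Eno1, Pfkl, Gpx4, Rsad2 and Timp1 were higher, at 6.13, 5.55, 0.34, 0.11, 0.32, 6.99 and 5.15. Few cells were left of 122 and 177, so with a pseudocount of 1 CPM the sizes of these ratios are not reliable.

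Across the 10 classes, 90 of 203 list and class pairs lay outside the central 95% of random lists, 40 above and 50 below. If genes and pairs were independent, 10.2 would lie there. They were not, since lists share members such as Tap1 and Ldha and all classes come from the same 2 libraries. The excess over 10.2 is therefore no measure of chance. The median of the dissociation stress list was below the random lists in 8 of 10 classes. It was -0.57 in plasmacytoid dendritic-like, -0.40 in conventional dendritic-like, -0.34 in B-like, -0.24 in regulatory T-like, -0.23 in CD4 T-like, -0.22 in CD8 T-like, -0.17 in monocyte-like and -0.08 in NK-like cells, with 12 of 13, 13 of 14, 12 of 14, 10 of 14, 11 of 14, 12 of 14, 8 of 14 and 9 of 14 genes lower. It was -0.02 in macrophage-like (percentile 62.0, 8 of 14 lower) and in melanoma-like cells (percentile 43.4, 10 of 14 lower), where it lay inside the random lists. In CD8 T-like cells Zfp36 was at a ratio of 0.775, Junb at 1.00 and Ier2 at 1.05. The NK-like median was inside the central 95% with equal weight per cell, at -0.082 (percentile 2.73), and without the most abundant cluster, at -0.040 (percentile 24.4). With equal weight per cell the stress median was -0.22 in B-like and -0.34 in CD8 T-like cells. In the main setting the cholesterol synthesis median also lay below the random lists in many classes. These were the CD8, CD4 and regulatory T-like, NK-like, macrophage-like, conventional and plasmacytoid dendritic-like and melanoma-like cells. It was thus no trait of any of these classes alone, and 1 library per group cannot tell a shift of the library from the knockdown. Lipid uptake genes had a median of 0.20 (percentile 99.5) in melanoma-like and -0.02 (percentile 46.7) in macrophage-like cells. Of the checkpoint ligand list 3 genes were measured in melanoma-like cells, with a median of 0.41 (percentile 99.6), which was 0.10 (percentile 96.35, inside the central 95%) with no UMI minimum. The lipid uptake median in melanoma-like cells was 0.069 (percentile 95.1) with no UMI minimum. With equal weight per cell it was 0.0055 (percentile 66.4) and the checkpoint median 0.58 (percentile 91.9), all 3 inside the central 95%. Myeloid chemokines had a median of 0.13 (percentile 98.6) in macrophage-like and -0.15 (percentile 0.22) in monocyte-like cells, which became 0.095 (percentile 95.8) with equal weight per cell and -0.10 (percentile 2.93) with no UMI minimum, both inside the central 95%.

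Of the 90 pairs, 45 stayed outside the central 95% with the same sign under every alternative run for lists and 45 did not under 1 or more. These alternatives varied pseudocounts, UMI minimums, scaling and the weight per cell, and in some pairs left out cells or the most abundant cluster. Doublet removal, the cell filter, the clustering and cells with proliferation genes were not varied in this count. Of the pairs not given above, these stayed. MHC class II genes had medians of -0.12 in CD8 T-like and -0.31 in plasmacytoid dendritic-like cells, and the first was -0.042 with a pseudocount of 50 CPM. Cholesterol synthesis genes were at -0.14 in NK-like, -0.27 in conventional dendritic-like and -0.41 in plasmacytoid dendritic-like cells, and the first was -0.050 with a pseudocount of 50 CPM. Glycolysis genes were at -0.12 in NK-like and -0.11 in regulatory T-like cells, inflammatory genes at 0.17 in monocyte-like cells, and alternative activation genes at 0.34 in conventional dendritic-like cells, 0.13 with no UMI minimum. The others lay inside the central 95% or changed sign under 1 or more alternatives. These were interferon gamma genes in NK-like (0.10) and regulatory T-like cells (0.17), myeloid chemokines in CD4 T-like (1.10), CD8 T-like (-0.072), NK-like (-0.11), conventional dendritic-like (0.12), plasmacytoid dendritic-like (-0.30) and melanoma-like cells (-0.19), and hypoxia genes in CD8 T-like (0.083), macrophage-like (-0.15) and melanoma-like cells (-0.18). They were also ferroptosis genes in B-like (-0.21) and regulatory T-like cells (-0.17), checkpoint ligands in B-like (-0.31) and NK-like cells (0.13), naive and memory genes in B-like (-0.27) and conventional dendritic-like cells (0.20), and proliferation genes in regulatory T-like (0.13) and conventional dendritic-like cells (-0.16). The last were inflammatory genes (-0.13) and lipid uptake genes (-0.12) in CD8 T-like cells, cholesterol synthesis genes in CD4 T-like cells (-0.43), NRF2 genes in regulatory T-like cells (0.22) and tissue residency genes in monocyte-like cells (0.20).

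Proliferation genes had a median of 0.03 (percentile 95.2) in CD8 T-like and -0.19 (percentile 1.78) in macrophage-like cells, the latter 0.20 (percentile 95.7) with equal weight per cell and -0.14 (percentile 16.4) without the most abundant cluster, both inside the central 95%. At equal depth, the share of macrophage-like cells with UMIs of 2 proliferation genes was 8.17% (5.36 to 11.8) in the control and 18.4% (13.9 to 23.5) in the knockdown library, with 69 and 47 cells left out as too shallow. CD8 T-like cells were at 47.8% (45.3 to 50.3) and 51.9% (48.9 to 54.8), with 12 and 7 left out. With 1 proliferation gene in place of 2, the intervals of both differences included 0, at 41.8% and 49.4% of macrophage-like cells (7.61 points, -0.808 to 15.9) and 70.9% and 73.9% of CD8 T-like cells (2.97 points, -0.462 to 6.36). NK-like cells were at 8.04% and 8.55%. Monocyte-like cells, the class with little proliferation used as background, were at 2.17% (1.27 to 3.44) and 3.33% (2.02 to 5.16), at median depths of 4797 and 6802 UMIs. Without thinning the macrophage-like shares were 34.1% and 54.5% at median depths of 2531 and 3383, the CD8 T-like shares 76.9% and 90.0% at 6481 and 11833, and the monocyte-like shares 29.2% and 43.4%.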

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

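The tests in this part were chosen only after the related values had been seen. In the knockdown library 21.8% (21.0 to 22.6) of barcodes had more than 10% mitochondrial UMIs, against 12.9% (12.3 to 13.5) in the control library. These 2080 and 1463 barcodes entered no comparison in the main setting. The looser cell filter, which allowed more mitochondrial UMIs, took in a part of them. They stand out because the share was higher in the knockdown library than in the control library. Melanoma cells past the CD45 sort that keep their marker RNA are argued against as the whole source of the excess of 848 barcodes. After each barcode was thinned to 500 UMIs, barcodes above the limit with UMIs of 2 T or NK cell genes and of no melanoma marker took 2.25% of the control and 4.59% of the knockdown library. The difference was 2.34 points (1.84 to 2.85), where an excess made of cells like the kept melanoma-like cells would give 0.0502. That value rests on 1 of 177 such cells passing, in a class named with the same markers that the gate forbids. It cannot speak for melanoma cells that lost their marker RNA, which stay open, as does a part supplied by other melanoma cells. UMIs of 3 or more melanoma markers were found in 6.11% of knockdown barcodes above the limit and 6.25% of the others, and in 4.99% and 3.54% in the control library, but barcodes above the limit were shallower, with medians of 1101 against 4573.5 and 857 against 3002 UMIs. Shallow or broken cells remain a possible explanation. The median of 1101 UMIs above the limit was 24.1% of the median of the other barcodes, and 28.5% in the control library. Barcodes above the limit were thus shallow in both libraries, so these values do not tell what made the excess. The knockdown of Decr2 stays open and untested as an explanation, with 1 library per group.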

How the results depend on the processing

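The alternatives that left out cells by UMIs of the gene, used deep melanoma-like cells alone, left out the 3 deepest of them or weighted cells equally for lists were chosen after seeing the data, and the others before. No paired analysis was possible because each group had 1 library. Scrublet's automatic threshold marked 0 barcodes, so that alternative equals no doublet removal and adds nothing. Of 183 shares, 167 stayed within their interval and 16 moved, with 0 reversed. The set-aside subcluster did not form with separate clustering, so it has no value there. Of 1524 log2 ratios of reported genes, 1200 stayed, 268 moved and 56 reversed. Of 1234 list medians, 1150 stayed, 80 moved and 4 reversed, and of 20 cycling shares 11 stayed and 9 moved. The cause of the values below was not tested unless named. Depth limits the scarce genes, and 6 of the named genes reversed without the single cell that held most of their UMIs.

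Differences in share, knockdown minus control in points, moved as follows. The stricter filter gave -0.766 for NK-like, 0.463 for monocyte-like and, of myeloid cells, -2.47 for macrophage-like cells. The looser filter gave -0.323 for macrophage-like cells, and separate clustering gave -2.85 of T-like cells for CD8 T-like cells, against 0.106 with the set-aside subcluster in the main clustering, so this compares classes drawn in different ways. Melanoma-like cells were at 0.264 under the stricter and 0.436 under the looser filter, against 1.21. CD4 T-like cells were at 3.95 of all cells and 11.4 of T-like cells with separate clustering, which named none in the control library, and at 1.69 of T-like cells under the looser filter. Other T-like cells were at -2.28 with doublets kept, also with the automatic threshold, and at -3.76 with separate clustering, or -11.8 of T-like cells. The set-aside subcluster was at 0.184 of all cells and 1.01 of T-like cells under the looser filter. Without thinning the cycling difference was 13.1 points in CD8 T-like and 20.3 in macrophage-like cells, where depth per cell is the cause by construction.

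Of list medians in melanoma-like cells, interferon gamma became 0.24 with equal weight per cell, 0.86 with a pseudocount of 1 CPM and 0.57 with 50 CPM. MHC class II became 0.41, 0.84 and 0.53 in that order. Type I interferon became 0.78 with 1 CPM and 0.41 with 50 CPM, MHC class I 0.22 with equal weight and 0.36 with 50 CPM, and cholesterol synthesis -0.30 with 50 CPM. With equal weight NRF2 became -0.30 (percentile 7.05, inside the central 95%) and myeloid chemokines reversed to 0.42. In CD8 T-like cells equal weight gave -0.13 for cholesterol synthesis, -0.17 for cytotoxic, -0.34 for stress and 0.35 for naive genes. There 50 CPM gave -0.15 for cholesterol synthesis, -0.14 for stress and 0.10 for naive genes, and 1 CPM gave 0.53 for naive genes. In macrophage-like cells equal weight gave -0.022 for cholesterol synthesis and 0.20 for proliferation. Members of 100 UMIs gave -0.0039 for alternative activation and 0.078 for cholesterol synthesis, from fewer genes. Type I interferon became 0.045 without the most abundant cluster.

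These genes reversed, given as log2 ratios. With doublets kept, Ccl3 (-0.077) and Il1b (-1.53) did so in CD4 T-like, Ccl8 (0.93) in monocyte-like, Cxcl10 (-0.95) in B-like, Cxcl10 (0.20) and Pf4 (0.13) in macrophage-like, Gzma (-0.69) in regulatory T-like and Ifit3 (-0.17) in conventional dendritic-like cells. Equal weight reversed Nfe2l2 (-0.12) in macrophage-like cells, and Cck (-0.78), Iigp1 (-0.23), Rsad2 (0.63), Sqstm1 (0.24), Tap1 (-0.31) and Tap2 (-0.43) in melanoma-like cells. The stricter filter reversed Cck (-5.89) in melanoma-like, Cxcl10 (-1.24) in B-like and Retnla (-0.092) in macrophage-like cells. Without the cell of each library with most UMIs of the gene, Cck (-4.21) and Timp1 (0.16) reversed in melanoma-like, Il1b (-1.20) and Spp1 (0.14) in CD4 T-like, Lyz2 (0.16) in plasmacytoid dendritic-like and Retnla (-0.60) in macrophage-like cells.

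Leaving out cells that had UMIs of 2 proliferation genes used counts without thinning, so it also removed cells by depth. Without these cells, Gzmf (-0.16) and Mt1 (-0.48) reversed in CD8 T-like cells. So did Acod1 (-2.14), Ccl4 (-0.36), Il1b (-2.29) and Spp1 (0.25) in CD4 T-like, Areg (-0.16) and Cd8b1 (0.68) in regulatory T-like, Hist1h1b (0.13) in NK-like, and Gbp2 (-0.14) and Mzb1 (-0.17) in B-like cells. Ccl8 (1.78) and Cxcl1 (-0.37) reversed in monocyte-like cells, and Chil3 (0.10), Cxcl10 (0.13), Lyz1 (-1.34), Retnla (-2.48) and Serpinb2 (0.80) in macrophage-like cells. In melanoma-like cells this setting removed 92 of 122 cells in the control and 106 of 177 in the knockdown library. There Cck (-3.54), Cxcl10 (-0.26), Eno1 (0.34), Gpx4 (0.32), Hmgcs1 (6.13), Idi1 (5.55), Iigp1 (-2.89), Pfkl (0.11), Phf11d (-0.32), Rsad2 (6.99), Tap1 (-0.72), Tap2 (-0.99), Tapbp (-0.10) and Timp1 (5.15) reversed.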

Other observations

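The tests of explanations in this part were chosen only after the related values had been seen. Among the T-like cells that were neither CD8, CD4 nor regulatory, the largest subcluster was led by Klra6, Trdc, Klra1 and Cd160, with a UMI of Trdc or Tcrg-C1 in 28.0% of its cells against 1.13% of B-like cells, at median depths of 3084.5 and 1909 UMIs. It made up 22.5% of control and 19.0% of knockdown T-like cells. A subcluster led by Ifit3, Ifit1 and Usp18 made up 3.17% and 3.23%, and an Il17a subcluster with Tcrg-C1 and Rora 2.54% and 2.41%. Of the macrophage-like cells, those with C1qa, C1qc and Ms4a7 made up 34.1% in the control and 32.5% in the knockdown library, and those with Inhba, Ptgs2 and Thbs1 65.9% and 67.5%.

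Rare cell types were counted as kept cells with UMIs of 3 or more list genes, with no thinning, so deeper cells of the knockdown library pass more easily. Non-classical monocyte genes were found in 2.62% (2.30 to 2.97) of control and 4.30% (3.83 to 4.81) of knockdown cells, and ILC2 genes in 0.101% and 0.290%. Neutrophil genes were found in 17 and 10 cells, plasma cell genes in 3 and 9, erythroid genes in 8 and 4, endothelial genes in 3 and 4, fibroblast genes in 3 and 1, and platelet genes in 0 and 1. Eosinophil and keratinocyte genes were found in 0 cells of both libraries, with upper limits of 0.0412% and 0.0536%. An unnamed cluster led by Gm26917, Utrn and Malat1, with a median of 829 UMIs and 6.81% mitochondrial UMIs, took 3.42% and 5.50% of kept cells.

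A cluster of 79 cells came almost wholly from the control library, with 75 control and 4 knockdown cells. Gzma was detected in 100% of its cells, Trbc1 in 87.3%, Cd3g in 78.5%, Ncr1 in 58.2% and Klrg1 in 38.0%, at a median of 1790 UMIs. In B-like cells of the control library, which should lack these genes, the shares were 13.9%, 5.83%, 6.15%, 0.647% and 0.324% at a median of 1543 UMIs. In T-like cells of the control library they were 25.9%, 55.6%, 92.1%, 3.73% and 6.56% at 3603 UMIs. Of its 5 cells with a UMI of a T cell receptor beta variable segment, 4 had Trbv17, against 5 of 342 such cells among the T-like cells of the control library.

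Interferon gamma genes were higher in melanoma-like cells of the knockdown library. RNA of immune cells in these droplets is argued against as the whole source. As a median over the list genes, the excess would need RNA of 1 immune class at 18.5% of its level there or more, the lowest being for monocyte-like cells. In that class Ptprc allowed 3.45%, with an upper limit of 4.24%, and the median over its markers was 0.508%. The share needed was above both shares in all 9 immune classes, and Iigp1 was at 330 CPM in melanoma-like cells of the knockdown library against at most 166 CPM in an immune class. The 3 deepest cells of each library, which held 10.8% and 16.6% of the UMIs, are argued against as the whole source, with a median of 0.64 without them against an upper limit of 0.12 for random lists. The knockdown of Decr2 in the tumour cells may be the cause, but with 1 library per group it cannot be told apart from any other difference between these tumours. Equal weight per cell left a median of 0.24, inside the central 95% of random lists, so the difference rests on the deep cells and was not shown for the shallow ones.

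The stress list lay below random lists in 8 of 10 classes of the knockdown library. Free RNA adding like amounts of Hspa1a to every droplet is argued against as the whole source in conventional dendritic-like cells. There the control excess was 5.31 (4.87 to 5.74) UMIs per cell, while B-like cells of the control library held 0.780 in all. A part from free RNA stays open. These UMIs were not scaled for depth. The control excess of -0.265 (-0.436 to -0.0980) in B-like cells therefore also follows depth, at medians of 1543 and 2563.5 UMIs. In NK-like cells the excess was -0.141 per cell, yet the CPM ratio was 0.711. In CD8 T-like cells the median was -0.22 under the stricter cell filter, below the lower limit of -0.07. Shallow cells weigh little in the summed UMIs of this class, with medians of 6481 and 11833 UMIs per cell. This filter therefore cannot decide on cells of low quality, which stay open. Handling of 1 tumour sample, such as time in the warm digest, may be the cause, with medians below random lists in 8 of 10 classes and inside them in macrophage-like (percentile 62.0) and melanoma-like cells (percentile 43.4), but 1 library per group keeps it and the knockdown open alike.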
